A study of Mus musculus with 4 samples.

How the data were processed

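RNA was measured in 4 libraries of mouse gliomaspheres, 2 untreated and 2 treated with 1 µM 4OH-TAM for 7 days. Per the labels' protocols, RNA was extracted with an automated column kit and libraries were made with a stranded polyA kit (TruSeq Stranded mRNA). The authors deposited whole-number read counts per gene in 1 table, with a column for each library. FastQC, STAR 2.5.3a and featureCounts on genome build mm10 (GRCm38) are named in the submitters' processing notes. The gene annotation, the strand setting of the counter and any treatment of reads with several matches are not given in the sources used here. Because the strand setting is not given, counts of genes that overlap another gene are uncertain. The deposited counts are not normalized. The table lists 13163 genes, and all of them exceed 1 CPM of the column total in at least 2 libraries, so genes below that level were left out before deposit. The table names genes by symbol, some of them older ones (Ctgf, Cyr61), and 12714 symbols (96.6%) matched GENCODE release M21 of GRCm38, from which gene identifiers and coordinates were taken.

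Each column was assigned to a library by its title, and groups were taken from the treatment label. The replicate letters A and B are given by the labels. The total counts were 28453438, 27170185, 24252026 and 24269298. The lowest count of a listed gene in any library was 1, and counting error is largest for genes near 1 CPM. The A and B libraries differed by more than sampling noise (chi-square per degree of freedom 2.09 for untreated and 1.55 for 4OH-TAM). They were kept as 2 replicates per group, although this spread does not show whether they came from separate cultures. The first principal component of log2 CPM held 91.6% of the variance and separated the groups.

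Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, glmQLFit and glmQLFTest) with 2 residual degrees of freedom, over the 4 libraries with treatment as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. filterByExpr removed no gene. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F statistic. CPM values were computed with TMM-scaled library sizes. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with adjustment over the 25 lists, and beside it with camera under an estimated correlation and with fry. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The 25 lists cover YAP/TAZ direct targets, Hippo components, DNA replication, mitosis, neural and glioma stem cells, astrocytes, oligodendrocyte lineage, neurons, mesenchymal glioma, extracellular matrix, focal adhesion and actin, ERK output, AP-1, p53 targets, interferon response, cholesterol synthesis, hypoxia and glycolysis, ATF4 and the unfolded protein response, MYC and ribosome biogenesis, inflammation, TGF-beta and BMP, Notch and Wnt, microglia, fibroblasts and endothelium. Of 789 list entries, 693 were listed in the table, 687 by symbol and 6 by an older symbol. In 7 lists fewer than 80% of the members were listed, and members that the table does not list were left out. The sets were taken from general knowledge and not from these samples.

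The named genes were Yap1 and Wwtr1; the 8 genes with the largest fold change in each direction among those with adjusted p under 0.05, a mean of at least 50 counts, groups that do not overlap in CPM and a symbol that is not a clone, predicted-gene or pseudogene name; up to 4 members of each list by size of fold change among those past the threshold, or the 2 with the highest mean count where none passed; and Cyr61, Ctgf, Ankrd1 and Axl. Names outside this rule are marked as chosen after their values were seen. Alternatives were median-of-ratios, upper-quartile and unscaled library sizes, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 50 counts, the replicate letter as a block, each library left out in turn, a test against a fold change of 1.5 and an adjusted p under 0.01; list members shared between lists were also left out. Ribosomal protein, respiratory chain and small RNA gene groups, Reactome sets shipped with fgsea 1.28.0 and direct targets of at least 10 CPM were added after the data were seen.

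The procedure was tested on simulated counts for the 13163 genes with the means, library sizes and trended dispersions of the real libraries. It called, in the right direction, 26% of 50 genes changed 1.1-fold, 86% of 50 changed 1.25-fold, 96% of 50 changed 1.5-fold and 98% of 50 changed 2-fold, and called 7 of 12923 unchanged genes. It called the 1 shifted list and 0 of 24 unshifted lists. Genes were simulated independently of each other and 12923 of them were unchanged. The simulation therefore does not show how the list test behaves with correlated members or when most genes change. Gene lengths and GC contents used in the closing section are those of the longest GENCODE M21 transcript of each gene.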

Results

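PolyA RNA sequencing was carried out on gliomaspheres, clusters of glioma-like cells grown in suspension in serum-free medium with EGF and bFGF at 20 ng/ml each. The spheres came from mouse astrocytes transformed with mutant KRas and a short hairpin RNA against p53. The astrocytes carried floxed alleles of Yap1 and of Wwtr1, the gene that encodes TAZ, together with a tamoxifen-inducible Cre recombinase. YAP and TAZ are transcriptional co-activators held in check by the Hippo kinase pathway and act mainly through TEAD factors on DNA. One group of 2 libraries came from spheres left untreated, and the other group of 2 libraries came from spheres exposed to 1 µM 4-hydroxytamoxifen (4OH-TAM) for 7 days. The single comparison of the design asks how the transcriptome of these spheres differs after YAP/TAZ deletion is induced. The total count was 28453438 and 27170185 in untreated libraries A and B, and 24252026 and 24269298 in 4OH-TAM libraries A and B, over 13163 listed genes. Values below are given as mean CPM ± SD with n = 2 libraries per group, and fold changes as 4OH-TAM over untreated. No label says that the A and B libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The estimated biological coefficient of variation was 1.97%, and the A and B libraries correlated at r = 0.998 in log2 CPM across genes in both groups.

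The floxed genes fell in both 4OH-TAM libraries. Wwtr1 (ENSMUSG00000027803.14, GRCm38 chromosome 3, 57455649 to 57575910, minus strand, protein-coding) had 10087 and 9546 counts in the untreated libraries and 1069 and 1069 counts in the 4OH-TAM libraries. Its level dropped from 362 ± 2.2 to 42.9 ± 0.096 CPM, which is 11.8% of the untreated level (log2 fold change -3.08 ± 0.036 SE, adjusted p = 1.7e-48, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Yap1 (ENSMUSG00000053110.13, chromosome 9, 7931999 to 8004596, minus strand, protein-coding) had 5249 and 4987 counts without treatment and 2289 and 2312 counts with it. Its level dropped from 189 ± 0.61 to 92.4 ± 0.45 CPM, which is 48.9% of the untreated level (log2 fold change -1.03 ± 0.033 SE, edgeR adjusted p = 3.5e-30). Whole-gene counts include reads from exons outside the floxed segment, and the labels do not name the deleted exons, so a remaining count does not measure the share of cells that kept the gene.

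Among established YAP/TAZ target genes, Cyr61 and Ctgf, both fixed in advance, fell, whereas Axl, also fixed in advance, rose. Amotl2, named for the size of its fold change, fell. The list as a whole went both ways. Cyr61 (current symbol Ccn1, a secreted matricellular protein; chromosome 3, 145646976 to 145649981) fell 6.32-fold, from 206 ± 2.6 to 32.5 ± 0.61 CPM (edgeR adjusted p = 4.4e-44). Ctgf (Ccn2, also matricellular; chromosome 10, 24595442 to 24598683) fell 13.5-fold, from 3.31 ± 0.52 to 0.241 ± 0.056 CPM (edgeR adjusted p = 8.8e-16), on 102 and 78 counts against 5 and 7. Amotl2, an angiomotin family scaffold that binds YAP (chromosome 9, 102716672 to 102733418), fell 3.15-fold, from 22.6 ± 2.2 to 7.18 ± 1.1 CPM. In the opposite direction, Axl, a receptor tyrosine kinase (chromosome 7, 25757273 to 25788705), rose 1.39-fold, from 185 ± 3.3 to 257 ± 11 CPM, and Nt5e, the CD73 ecto-nucleotidase, rose 2.07-fold from 1.40 ± 0.046 to 2.91 ± 0.14 CPM. Igfbp3, chosen after its values were seen as the most abundant member of the list, rose 1.87-fold to 5656 ± 27 CPM. Of the 26 listed members of the 28-gene target list, 13 rose, 8 fell and 5 did not pass the threshold. The list median was 0.14 and its mean -0.11 on the log2 scale, and the list did not pass the test against other genes (camera adjusted p = 0.43). Ankrd1, another classical target fixed in advance, is not among the listed genes and was not analysed here.

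**Figure D1:**
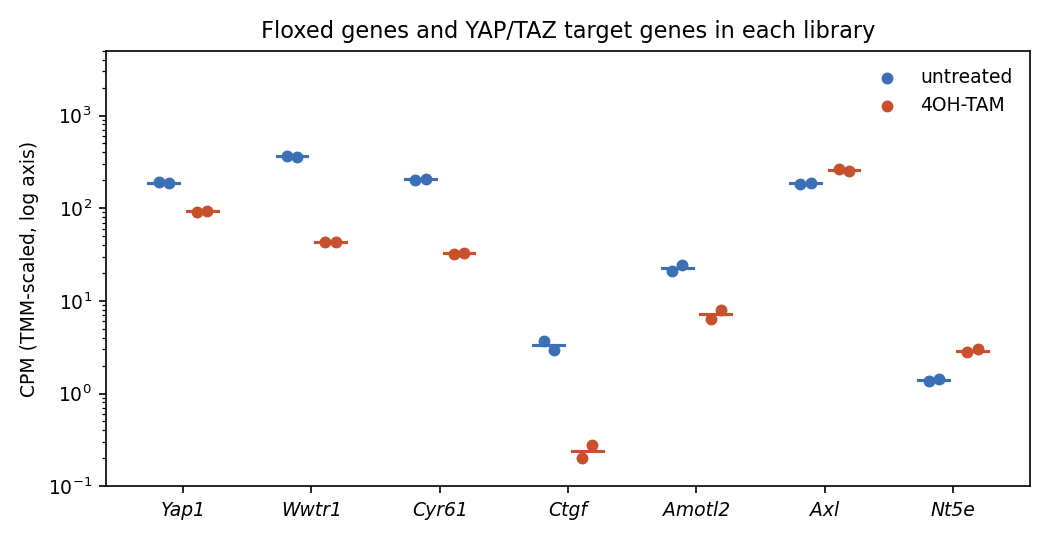
CPM scaled by TMM factors, on a log axis, for the floxed genes Yap1 and Wwtr1 and for 5 YAP/TAZ target genes, with 1 point per library (2 untreated, 2 4OH-TAM) and a horizontal bar at each group mean. Yap1, Wwtr1, Cyr61, Ctgf and Amotl2 are lower in both 4OH-TAM libraries than in both untreated libraries, and Axl and Nt5e are higher in both.

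Components of the Hippo pathway went both ways. Of 22 listed components, 12 rose, 6 fell and 4 did not pass, and the list did not pass the test against other genes (camera adjusted p = 0.33). Vgll4, a TEAD cofactor that competes with YAP, fell 2.02-fold from 28.2 ± 0.11 to 14.0 ± 0.40 CPM, and Rassf1 fell 1.53-fold. The giant protocadherin genes Fat4 and Fat1 rose by 0.92 and 0.59 on the log2 scale, the latter from 298 ± 21 to 448 ± 14 CPM.

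Across the transcriptome, 4504 genes were higher and 4523 lower in 4OH-TAM libraries at an adjusted p under 0.05 (edgeR quasi-likelihood test), which is 68.6% of the 13163 genes tested. Most of these differences were small, with a median absolute log2 fold change of 0.35 among the genes called. At least 2-fold changes were called for 509 genes in the upward direction and 174 in the downward direction, and at least 4-fold changes for 36 and 18 genes. When the test was made against a fold change of 1.5 (edgeR glmTreat), 795 genes were higher and 396 lower. The groups did not overlap for 83.4% of the genes, where chance alone gives 33.3% with 2 libraries against 2. With library totals alone in place of TMM factors, 61.2% of called genes were higher, against 49.9% in the main test.

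Among genes with a mean of at least 50 counts and groups that do not overlap, the 8 with the largest increases were low in untreated spheres, at no more than 4.53 CPM. Calb1, a neuronal calcium-binding protein (chromosome 4, 15881264 to 15908064), rose 9.93-fold from 0.557 ± 0.23 to 5.54 ± 0.50 CPM (edgeR adjusted p = 2.2e-18). Crym rose 8.20-fold, the glutamate receptor gene Grm6 8.06-fold and the basement membrane collagen gene Col15a1 6.61-fold. Rbp1, a cellular retinol-binding protein (chromosome 9, 98422961 to 98446575), rose 6.43-fold from 4.53 ± 0.63 to 29.2 ± 0.80 CPM. The polysialyltransferase gene St8sia2 rose 5.95-fold, the serotonin receptor gene Htr1b 5.69-fold and the desmosomal plakophilin gene Pkp1 5.23-fold. Among genes with at least that mean count, the largest decreases after Wwtr1 were those of Thy1, a cell surface glycoprotein of neurons and fibroblasts (chromosome 9, 44043384 to 44048579), which fell 6.33-fold from 95.1 ± 1.4 CPM to 15.8% of that level (edgeR adjusted p = 3.1e-38), and of Cyr61. Tnfsf18 fell 4.97-fold, the zinc finger factor gene Myt1 4.49-fold, the lysozyme gene Lyz2 3.95-fold, Ddn 3.72-fold and Spon1 3.37-fold. Lyz2 has a close paralog, and its counts are uncertain to the extent that reads are shared with it.

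Most genes of the DNA replication and mitosis lists rose. Of 40 replication genes, 32 rose, 1 fell and 7 did not pass (33 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.75. Tk1, which makes thymidine nucleotides for DNA synthesis, rose 3.69-fold from 2.11 ± 0.17 to 7.79 ± 0.017 CPM, the replication licensing factor gene Cdc6 rose 3.54-fold, the helicase component gene Gins1 3.68-fold and the polymerase epsilon gene Pole 3.07-fold from 8.28 ± 0.53 to 25.4 ± 2.3 CPM. Of 40 mitosis genes, 36 rose, 1 fell and 3 did not pass, with a median log2 fold change of 0.65. The proliferation marker Mki67 rose 2.04-fold from 53.1 ± 3.0 to 108 ± 0.13 CPM, the kinetochore genes Cenpf and Bub1 each rose 2.07-fold, and the kinesin gene Kif2c rose 1.94-fold. Both lists passed the competitive test with its preset correlation of 0.01 (camera adjusted p = 8.9e-09 for each). Neither passed with an estimated correlation (camera adjusted p = 0.33 for each). The estimated correlation was 0.0102 for replication, close to the preset, and 0.0317 for mitosis. With an estimated correlation camera tests on the 2 residual degrees of freedom and so needs a larger shift, here and for the lists below. For 19 of the 25 lists, mitosis among them, the counts of members that rose and fell were the same when adjusted over the list alone; for the others both counts are given.

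Markers of neural stem and glioma stem cells rose more often than they fell. Of 31 markers, 17 rose, 6 fell and 8 did not pass, and the list did not pass the test (camera adjusted p = 0.077). Nes, the intermediate filament of neural progenitors, rose 1.91-fold from 522 ± 14 to 997 ± 7.8 CPM, and the Notch effector gene Hes1 and Notch1 rose 2.02-fold and 1.75-fold. Egfr fell 1.60-fold from 77.3 ± 2.9 to 48.4 ± 0.82 CPM. Sox2, a core stem cell factor chosen after its values were seen, rose 1.13-fold from 287 ± 2.0 to 323 ± 2.5 CPM.

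Astrocyte markers went both ways, with more falling than rising. Of 27 listed markers, 8 rose, 15 fell and 4 did not pass (9 rose and 15 fell adjusted over the list alone; camera adjusted p = 0.33). Gfap, the astrocyte intermediate filament, rose 1.93-fold from 227 ± 1.1 to 439 ± 4.0 CPM and the potassium channel gene Kcnj10 rose 2.18-fold, whereas the secreted chaperone gene Clu fell 2.34-fold from 219 ± 7.6 to 93.8 ± 0.22 CPM and the angiotensinogen gene Agt fell 4.45-fold to 0.361 ± 0.00081 CPM. Of 19 listed oligodendrocyte lineage markers, 5 rose, 9 fell and 5 did not pass (camera adjusted p = 0.33); Ptgds fell 3.16-fold and Lhfpl3 2.24-fold, while the progenitor factor gene Nkx6-2 and C1ql1 rose 3.09-fold and 3.02-fold. Of 24 listed neuronal markers, 13 rose, 7 fell and 4 did not pass (camera adjusted p = 0.17). The neuronal tubulin gene Tubb3 rose 3.03-fold to 4.03 ± 0.19 CPM, Elavl2 rose 2.53-fold and the neurofilament gene Nefl rose 2.43-fold from 26.7 ± 0.019 to 64.9 ± 1.8 CPM. Dcx, a marker of migrating neuroblasts, fell to 0.722 ± 0.51 CPM, with a log2 fold change of -1.68 that was -1.10 without 4OH-TAM replicate A and -2.67 without 4OH-TAM replicate B.

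Genes of the mesenchymal glioma state and of cell adhesion rose more often than they fell. Of 34 mesenchymal genes, 23 rose, 6 fell and 5 did not pass (camera adjusted p = 0.0037; adjusted p = 0.35 with an estimated correlation). Tgfbi, a secreted adhesion protein, rose 3.71-fold from 15.4 ± 0.22 to 57.3 ± 1.7 CPM, the plasminogen activator inhibitor gene Serpine1 rose 2.38-fold from 97.3 ± 2.1 to 231 ± 3.1 CPM, Thbs1 rose 1.98-fold and S100a6 rose 1.85-fold. Vim, chosen after its values were seen, rose 1.57-fold to 5489 ± 34 CPM. Of 51 listed focal adhesion and actin cytoskeleton genes, 31 rose, 11 fell and 9 did not pass (camera adjusted p = 0.0081; adjusted p = 0.33 with an estimated correlation). The scaffold gene Nedd9 rose 1.96-fold, the integrin gene Itga1 1.75-fold and the adhesion protein gene Tes 1.69-fold, and Fhl2 rose 1.69-fold at 1.47 ± 0.20 CPM, a call that DESeq2 did not make (adjusted p = 0.16) and that was lost without 4OH-TAM replicate B (edgeR adjusted p = 0.10). Of 41 listed extracellular matrix genes, 21 rose, 13 fell and 7 did not pass (camera adjusted p = 0.14). Fbln5 rose 3.47-fold, the crosslinking enzyme gene Lox 2.65-fold and Thbs2 2.22-fold from 104 ± 0.43 to 231 ± 3.4 CPM, whereas the elastin gene Eln fell 3.08-fold.

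**Figure D2:**
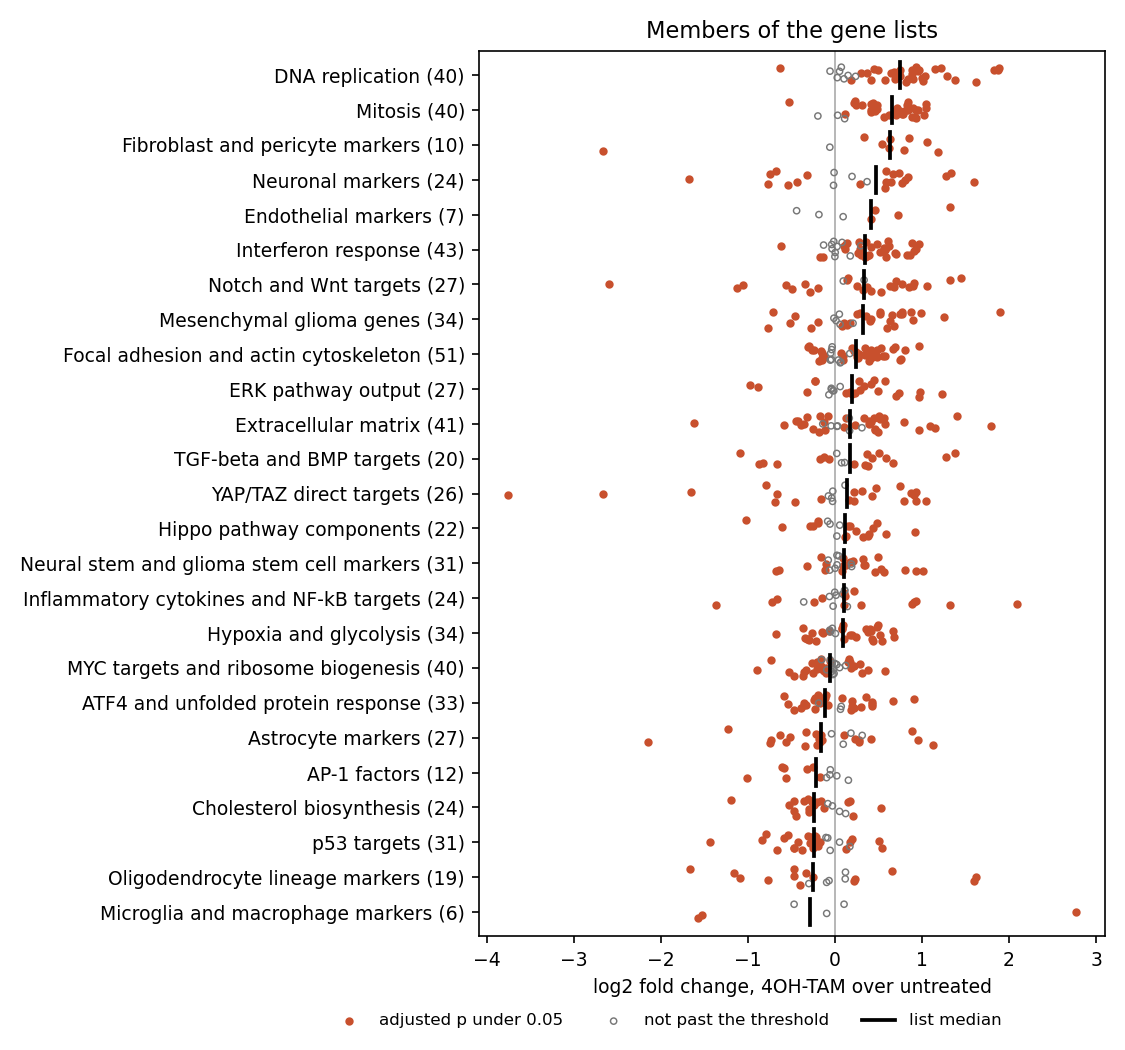
Log2 fold change of 4OH-TAM over untreated (x axis) for each listed member of the 25 gene lists (y axis, number of members in brackets), with filled points for an adjusted p under 0.05, open points for the rest and a black bar at the list median. DNA replication (median 0.75) and mitosis (median 0.65) stand highest, and the YAP/TAZ direct targets reach from -3.76 to 1.05.

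Targets of p53 and AP-1 factors fell more often than they rose, and interferon response genes rose more often than they fell. Of 31 p53 targets, 21 fell, 5 rose and 5 did not pass (22 fell and 5 rose adjusted over the list alone; camera adjusted p = 0.0056; adjusted p = 0.33 with an estimated correlation). The stress cytokine gene Gdf15 fell 2.70-fold, the apoptosis inducer gene Bbc3 1.79-fold, Zmat3 1.73-fold from 194 ± 1.9 to 112 ± 0.99 CPM and Eda2r 1.58-fold. Cdkn1a, which encodes the cell cycle inhibitor p21 and was chosen after its values were seen, fell by 0.59 on the log2 scale from 396 ± 1.2 to 264 ± 0.82 CPM. Of 12 listed AP-1 and related bZIP factors, 7 fell, 0 rose and 5 did not pass (camera adjusted p = 0.036; adjusted p = 0.35 with an estimated correlation), and the call was lost without untreated replicate A (camera adjusted p = 0.051). Mafk fell 2.02-fold, Maff 1.53-fold and Atf7 1.48-fold, and Jund fell by 0.59 on the log2 scale. Of 43 listed interferon response genes, 30 rose, 3 fell and 10 did not pass (camera adjusted p = 9.7e-05; adjusted p = 0.33 with an estimated correlation). Cmpk2 rose 1.95-fold, Parp14 1.91-fold, and the interferon-inducible GTPase genes Irgm1 and Iigp1, members of a family with similar copies and so with uncertain counts, rose 1.88-fold and 1.85-fold.

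The ERK output, Notch and Wnt, TGF-beta and BMP, and inflammatory lists did not pass the list test, and their members went both ways. Of 27 listed ERK output genes, 16 rose, 5 fell and 6 did not pass (camera adjusted p = 0.077); the cytokine gene Lif rose 2.34-fold, Egr3 and the EGF receptor ligand gene Areg each rose 1.96-fold, and the receptor gene Epha2 fell 1.97-fold. Of 27 listed Notch and Wnt genes, 17 rose, 8 fell and 2 did not pass (camera adjusted p = 0.077). The Notch ligand genes Dll4 and Dll1 moved apart, with a 2.49-fold rise and a 2.19-fold fall, and the Wnt-related genes Lef1 and Lgr5 did likewise, with a 2.73-fold rise and a 6.06-fold fall to 0.261 ± 0.029 CPM. Of 20 listed TGF-beta and BMP genes, 10 rose, 7 fell and 3 did not pass (camera adjusted p = 0.33); Pmepa1 and the activin gene Inhba rose 2.61-fold and 2.42-fold, and Bambi and Bmp7 fell 2.13-fold and 1.83-fold. Of 24 listed inflammatory genes, 10 rose, 5 fell and 9 did not pass (camera adjusted p = 0.33). The chemokine gene Cxcl2 rose 4.27-fold to 1.83 ± 0.024 CPM, Tnfaip2 2.49-fold and Birc3 1.90-fold, and the chemokine gene Ccl7 fell 2.58-fold.

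Genes of cholesterol synthesis fell more often than they rose, and the other metabolic and stress lists did not pass the list test. Of 24 listed cholesterol synthesis genes, 16 fell, 4 rose and 4 did not pass (17 fell and 5 rose adjusted over the list alone; camera adjusted p = 0.017; adjusted p = 0.35 with an estimated correlation). Insig1, a sterol-responsive regulator of the pathway, fell 2.29-fold from 375 ± 7.8 to 164 ± 0.20 CPM, Idi1 fell 1.44-fold and Sqle, squalene epoxidase, 1.39-fold, whereas the mevalonate kinase gene Mvk rose 1.44-fold. Of 34 listed hypoxia and glycolysis genes, 19 rose, 11 fell and 4 did not pass (camera adjusted p = 0.33); Egln3 and Ankrd37 rose 1.60-fold and 1.59-fold, Hk2 rose 1.46-fold, and Gpi1 fell 1.60-fold from 3887 ± 11 to 2432 ± 39 CPM. Of 33 listed ATF4 and unfolded protein response genes, 12 rose, 18 fell and 3 did not pass (13 rose and 18 fell adjusted over the list alone; camera adjusted p = 0.33); Chac1 and Cth rose 1.87-fold and 1.59-fold, the chaperone gene Hspa5 fell by 0.58 on the log2 scale, and Ddit3 fell 1.45-fold. Of 40 MYC target and ribosome biogenesis genes, 9 rose, 18 fell and 13 did not pass (camera adjusted p = 0.18). Gnl3, a nucleolar GTPase, fell 1.85-fold, Ppan 1.66-fold and Tbrg4 1.44-fold, and Bop1 rose 1.49-fold. The share of counts on the ribosomal RNA precursor Rn45s was 0.483% and 0.521% in the untreated libraries and 0.357% and 0.355% in the 4OH-TAM libraries.

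Markers of cell types other than neural cells were few and moved in different directions. Of 6 listed microglia and macrophage markers, from a list of 20, Tmem119 rose 6.84-fold to 1.16 ± 0.059 CPM, Cd68 fell 2.98-fold from 190 ± 0.029 to 63.7 ± 2.2 CPM, Ctss fell 2.88-fold and 3 did not pass (camera adjusted p = 0.33). Of 10 listed fibroblast and pericyte markers, 8 rose, 1 fell and 1 did not pass (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.077). Notch3 rose by 0.85 on the log2 scale from 137 ± 4.6 to 246 ± 7.0 CPM, Lrrc15 2.26-fold and Islr 2.08-fold, and Thy1 fell as given above. Of 7 listed endothelial markers, 4 rose and 3 did not pass (camera adjusted p = 0.28). The VEGF receptor gene Flt1 rose 2.49-fold from 65.4 ± 0.77 to 163 ± 0.96 CPM, Egfl7 1.65-fold and Plvap 1.37-fold, and Esam rose 1.33-fold, a call lost under DESeq2 (adjusted p = 0.11), without untreated replicate B (edgeR adjusted p = 0.077) and without 4OH-TAM replicate A (edgeR adjusted p = 0.26). In all, 8 of 25 lists passed camera with the preset correlation, 5 upward and 3 downward, and 0 passed with the correlation estimated, where 3 had an unadjusted p under 0.05, while the rotation test fry, which does not compare a list with other genes, called 23. All differences described here are between spheres with and without 4OH-TAM, and no library with the drug but without floxed genes was analysed here.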

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

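The test of direct targets with at least 10 CPM was chosen after the data were seen, and that list did not pass there either. Under each of the 3 other scalings, limma-voom, DESeq2, no filter and the stricter filter, Wwtr1 and Yap1 kept their direction and their call, as they did with each library left out. The number of genes called was 9012 with median-of-ratios factors, 9051 with upper-quartile factors, 9035 with library totals, 9022 with limma-voom, 6915 with DESeq2 and 7588 to 8460 with a library left out, where a lone library is assumed to vary like the other group. The test against a fold change of 1.5 left 1191 genes, 795 higher and 396 lower, because it asks for a larger change. With a mean of at least 50 counts required, 107 genes were at least 2-fold lower in place of 174, since fewer genes were tested. The filter-free run removed nothing and so tests nothing. The replicate letters do not pair the libraries by any label, and the A minus B differences of the groups correlated at -0.024 across genes. With the replicate block 9008 genes were called, and the fibroblast and pericyte list passed (camera adjusted p = 0.0499, against 0.077 in the main test and 0.056 to 0.17 under the other alternatives with the preset correlation); no other list call changed with it. The AP-1 list lost its call without untreated replicate A (0.051, against 0.014 to 0.046 under the other alternatives with the preset correlation). The count of lists past the threshold was 8 in the main test, 0 with estimated correlations and 23 with fry. With the correlation estimated, camera tests on the 2 residual degrees of freedom and so needs a larger shift, and fry does not compare a list with other genes. Of 1394 values of 117 named genes other than the floxed ones under the alternatives, 1389 had the same direction and call, 5 lost the call (Fhl2 and Esam) and 0 reversed. Most of these genes were picked from the same data for large fold changes, so their kept calls say little about other genes. The 1394 values include the filter-free run, which repeats the main test. Limma-voom added calls for 4 lists: neural stem markers, extracellular matrix, ERK output, and Notch and Wnt. The stricter filter added calls for 2 lists, the Notch and Wnt list and the endothelial list. The cause of these added calls was not tested. No list changed direction under any alternative run on it. Depth limits genes near 1 CPM. Gins1, Fhl2, Cxcl2, Tmem119, Agt, Lgr5 and Lrrc15 had means of 16.8 to 30 counts. Their fold changes had standard errors of 0.25 to 0.38 on the log2 scale. The SD of Agt in 4OH-TAM rests on 9 and 9 counts and does not show the counting error.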

Other observations

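All tests of explanations in this part were chosen after the result was seen, as were the added gene groups and the Reactome sets. Of the genes of translation and mitochondrial respiration, which the fixed lists did not cover, more fell than rose in the 4OH-TAM libraries. Of 75 ribosomal protein genes, 73 fell and 2 rose, with a median log2 fold change of -0.66 (camera p = 2.7e-19; p = 0.25 with an estimated correlation). Of members chosen after their values were seen, Rps19 fell from 270 to 139 CPM (log2 fold change -0.96) and Rpl36 from 204 to 105 CPM (-0.96). The 2 that rose were Rps4l (1.05) and Rpl7l1 (0.32). The group was taken by gene symbol alone, which also admits genes named as like a ribosomal protein, such as these. Ribosomal protein genes took 3.94% and 4.14% of counts in the untreated libraries and 2.75% and 2.70% in the 4OH-TAM libraries. Of 82 nuclear-encoded respiratory chain genes, 66 fell and 3 rose, with a median of -0.30 (camera p = 1.4e-10; p = 0.24 with an estimated correlation). Among 664 Reactome sets of 15 to 300 genes, 29 were lower and 19 higher (camera adjusted p under 0.05), and 0 passed with an estimated correlation, where 0 had an unadjusted p under 0.05. Translation elongation held 80 genes, all 80 of which fell (camera adjusted p = 9.7e-19, and 0.80 with an estimated correlation). The overlap of this set with the ribosomal protein genes was not counted, so it cannot be read as a separate observation. The citric acid cycle set held 18 genes, of which 12 fell and 1 rose (camera adjusted p = 0.018; adjusted p = 0.80 with an estimated correlation).

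In Reactome sets of cilium assembly, more genes rose than fell. Intraflagellar transport held 37 genes, of which 26 rose and 3 fell (median log2 fold change 0.27, camera adjusted p = 0.015; adjusted p = 0.80 with an estimated correlation), and assembly of the primary cilium held 151, of which 85 rose and 25 fell (camera adjusted p = 0.018; adjusted p = 0.80 with an estimated correlation). Tubulin folding held 16 genes, of which 13 rose and 1 fell (camera adjusted p = 0.0038; adjusted p = 0.80 with an estimated correlation).

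Replication and mitosis genes were higher by a median of 0.70 over 80 genes. Fold changes also followed expression level across all genes (Spearman rho = -0.26 across genes, which are not independent), with a median of 0.29 in the lowest decile of log2 CPM and -0.11 in the highest. Against the 20 nearest genes in expression, transcript length and GC, the proliferation genes were still higher by a median of 0.61 (95% bootstrap interval over genes 0.47 to 0.80), which argues against that trend as the whole cause. An effect of 4OH-TAM or of Cre activity in place of YAP/TAZ loss cannot be told apart from the deletion, since 0 of the 4 libraries have the drug without the floxed genes. A change in the share of dividing cells after YAP/TAZ loss stays open and was not tested.

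Direct targets moved both ways. Of the 13 members that rose, 7 did so by 1.5-fold or more. Cells that kept both floxed genes would weaken a fall but raise nothing, so such cells alone do not account for those 7. That follows from the premise and is not a test, since the 13 were picked because they rose. Whether cells that kept Yap1 alone could raise a target was not tested. These 13 stood above their 20 nearest genes by a median of 0.59, but they were picked because they rose, so a trend with expression, length or GC cannot be told apart from a response of these genes. The 10 targets that did not pass or fell less than 2-fold were at 57.7% (Ajuba) or more of their untreated level. Wwtr1 was at 11.8%. These 10 were picked because they fell little, so their place above Wwtr1 was fixed in advance and tests nothing. Cyr61 at 15.8% and Ctgf at 7.39% are members of the same list that fell further. At unchanged levels per cell, cells that kept both floxed genes could leave only about 11.8% of a target that needs YAP/TAZ. That is reasoning from the Wwtr1 level and not a test. Cells that kept Yap1 alone cannot be told apart from independence of YAP/TAZ, because Yap1 stayed at 48.9% and its counts may include exons outside the deletion. Regulation of these genes by other factors was not tested.

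The fall of ribosomal protein genes may have a technical part. The median log2 fold change was -0.16 in the decile of shortest transcripts (median length 1108 bases) and 0.065 in that of the longest. The median log2 fold change of the ribosomal protein genes was -0.66. Against the 20 nearest genes of each, the median difference was -0.44 (interval -0.46 to -0.40), so the trend does not cover the whole fall. The choice among the 4 scalings tried does not cover it either, since the highest ribosomal protein median was -0.58. These scalings placed the median of all genes between -0.00023 and 0.077, so they could move the fall only a little. Beside this fall, 24 of 30 small nucleolar and spliceosomal RNA genes fell and 0 rose (median -1.08, camera p = 5.2e-09; p = 0.024 with an estimated correlation), and the Rn45s share went from 0.483% and 0.521% to 0.357% and 0.355%. Rn45s is a ribosomal RNA precursor and not a short RNA, and the kit selects polyA RNA. Neither value therefore shows how well short RNA was recovered. A lower recovery of short RNA in the 4OH-TAM libraries, beyond what annotated length captures, stays open. A lower demand for translation after YAP/TAZ loss also stays open, and neither was tested.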
